A study of Mus musculus with 24 samples.

How the data were processed

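Total visceral adipose tissue of mice aged 27 to 33 weeks was profiled by RNA sequencing in 6 groups of 4 libraries, 24 libraries in all. The groups were females and males of 3 genotypes. In one knockout Pparg, a nuclear receptor for fatty acids, was deleted in cells that express Cre recombinase from the Foxp3 locus, which are regulatory T cells. In the other, Tbx21, the gene of the transcription factor T-bet, was deleted in the same cells. Controls carried the Foxp3 Cre alone. RNA was extracted with a lipid tissue kit and libraries were made with a TruSeq RNA kit. The submitters' titles number 2 samples per group in each of 2 batches, so each group held 2 libraries of each batch. In the text, replicates 1 and 3 are the batch 1 libraries and replicates 2 and 4 the batch 2 libraries. The source name of control female replicate 1 gives the number and batch of replicate 4; the title was followed, and the source name's batch was tried as an alternative. Nothing in the sources used here says whether the libraries come from separate animals, so p-values measure the spread between libraries.

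The counts are deposited as 1 table of raw counts for 27179 genes with Entrez identifiers, made by the authors with featureCounts on builds GRCm38 and mm10, per the submitters' processing notes. The aligner, the annotation and all versions are not given in the sources used here. Of these genes, 1029 (3.79%) had no symbol; they held 0.433% of counts and were kept in the tests but not named. The log2 FPKM values are deposited as 24 tables of 15764 genes each, computed by the authors; their offset for zero counts and any further scaling between libraries are not stated, and they were used only for 1 alternative test. They were checked against the counts and carried the same batch differences, so they were not corrected for batch. Positions come from a RefSeq gene table for GRCm38, which matched 25275 genes by Entrez identifier.

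Library totals ranged from 8345575 to 31022845 counts. Reads are not independent molecules, so counting intervals cover counting error only. The common biological coefficient of variation was 0.404.

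Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr by group (17824 tested), scaled by TMM (trimmed mean of M values), and tested with the robust quasi-likelihood F test over all 24 libraries, with 6 groups and batch as a covariate (17 residual degrees of freedom). There were 9 comparisons: each knockout against control in each sex, males against females in each genotype, and for each knockout the difference between its effect in males and in females. The Benjamini-Hochberg adjusted p was called under 0.05 over all genes tested. Both knockouts share the same control libraries, so their results are not independent. Levels are TMM-scaled CPM (counts relative to the scaled library total) as mean ± SD of 4 libraries. Log2 fold changes are given with their standard error (SE). Log2 CPM used a prior count of 2. Against a group with 0 counts a fold is a lower bound computed from a floor of 3 counts over the group, and with 1 to 3 counts it is a ratio with its counting interval.

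These choices were made before the data were examined: the model, the comparisons, the gene lists, the alternatives except those named below, and the rule for which genes are named. The rule names Pparg, Tbx21 and Foxp3 always, and in comparisons of sexes also Xist, Ddx3y, Uty, Kdm5d and Eif2s3y. It then names up to 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap between the groups after removing the batch mean; the overlap condition was not used for differences of effects. It also names up to 4 members with the smallest adjusted p from each called list. Predicted genes, clones, pseudogenes and variable segments of antigen receptors were counted but not named. Genes named outside the rule were chosen after their values were seen, and the text says so. Some genes that the rule names, among them a gene with an outlying library, are not reported here, though every count includes them.

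There were 29 lists holding 445 genes, of which 409 were tested: pan T cell; regulatory T cell; type 1 and cytotoxic lymphocyte; type 2 immunity and eosinophil; B cell and plasma cell; macrophage; lipid-associated macrophage; inflammatory cytokine and chemokine; interferon response; antigen presentation and dendritic cell; neutrophil and mast cell; mature adipocyte; de novo lipogenesis; cholesterol synthesis; insulin signalling; thermogenic adipocyte; oxidative phosphorylation; extracellular matrix; adipose stromal progenitor; endothelial cell; mesothelium; lymph node stroma; male reproductive tract; female reproductive tract; mammary and other epithelium; skeletal muscle, pancreas and blood; cell cycle; immediate early and stress; and circadian clock. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of each comparison (261 tests in all). Camera was repeated with an estimated correlation, and fry tested whether a list moved on balance one way. Camera called 103 of the 261 tests; 3 of them held with an estimated correlation, and fry called 18.

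The alternatives were no batch term, the source name's batch for control female replicate 1, DESeq2 1.42.0, limma voom with quality weights, limma on the deposited log2 FPKM, RLE size factors, no low-count filter, a replicate block in place of batch, same-numbered libraries summed (12 samples), only the groups compared, leaving out each library, fry, and camera with an estimated correlation. Chosen after seeing the data were a batch term in each sex, each batch alone, leaving out 3 libraries with transcripts of other tissues, and leaving out the 8 libraries with more than 10 CPM of Foxj1, a gene of ciliated epithelium. Residuals over 2000 variable genes of the 12 same-numbered pairs correlated between −0.69 and 0.1, none above the preset limit of 0.5. The 24 libraries were kept separate. Batch left in the residuals can lower this, so equal numbers in both batches may denote 1 sample. None of the 36 pairs of libraries within a group was a copy; pairs across groups were not tested.

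The tests were run on simulated data with 200 changed genes. In Tbet knockout females, 14.9%, 64.2% and 86.4% of genes with a log2 change of 0.5, 1 and 2 were recovered. The shares were 16.4%, 52.2% and 83.3% for sex in controls and 1.49%, 31.3% and 75.8% for the Tbet difference between sexes. Of the lists, only the shifted lipogenesis list was called. Genes were drawn independently, so correlated lists were not tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.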

Results

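The 24 libraries of mouse visceral fat held from 14250142 to 30769949 counts in control females and from 15789476 to 24775804 in control males. Pparg knockouts held from 13371068 to 31022845 counts in females and from 15473451 to 27192326 in males. Tbet knockout females included the shallowest libraries, from 8345575 to 25882749 counts, and Tbet knockout males held from 12551619 to 27520628. Each group has n = 4 libraries, 2 of each batch, and all errors on levels are SD.

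Pparg, the nuclear receptor that drives adipocyte differentiation and was deleted only in regulatory T cells, was expressed across whole fat at similar levels in every group. It averaged 210 ± 134 CPM in control females, 217 ± 61.2 CPM in Pparg knockout females and 191 ± 43.4 CPM in Tbet knockout females. In males it averaged 245 ± 26 CPM in controls, 251 ± 24.5 CPM in Pparg knockouts and 231 ± 40.1 CPM in Tbet knockouts. Tbx21, which encodes the type 1 lymphocyte regulator T-bet, stayed near 1 CPM. Its means were 0.937 ± 0.352 CPM in control females, 1.11 ± 1.14 CPM in Pparg knockout females and 1.34 ± 0.89 CPM in Tbet knockout females. In males they were 1.17 ± 0.462, 1.46 ± 0.148 and 0.602 ± 0.526 CPM. Foxp3, the lineage factor of regulatory T cells, ranged in group mean from 0.387 ± 0.255 CPM in control females to 0.873 ± 0.55 CPM in Pparg knockout males. No called change of Pparg, Tbx21 or Foxp3 was found in any of the 9 comparisons. Adipocytes express Pparg and other lymphocytes express Tbx21, so these bulk levels do not check the genotype labels.

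In Pparg knockout females, the imprinted gene Mest, a marker of fat tissue expansion, rose, and so did Fam217a, a gene of little known function. Ide, which encodes insulin-degrading enzyme, fell. These were the only called genes, 2 higher and 1 lower of 17824 tested, while 2128 genes had an unadjusted p under 0.05.

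Mest (chromosome 6, 30733506 to 30748466) averaged 248 ± 218 CPM in Pparg knockout females against 23.2 ± 10.1 CPM in control females, a log2 fold change of 3.30 (SE 0.53, adjusted p = 0.0395). Fam217a (chromosome 13, 34909959 to 34924358) averaged 8.55 ± 2.84 against 3.43 ± 1.41 CPM (log2 fold change 1.32, SE 0.22, adjusted p = 0.0417). Ide (chromosome 19, 37268743 to 37334544) averaged 76.0 ± 6.51 against 142 ± 25.9 CPM (log2 fold change −0.88, SE 0.14, adjusted p = 0.0395). In batch 1 alone, with 0 genes called, the log2 fold changes were 2.202, 1.414 and −0.695 in this order, and in batch 2 alone, with 69 genes called, 3.942, 1.259 and −1.079. The calls depended on single libraries. The count was 28 without Pparg knockout female replicate 1 and 20 without replicate 3, and 0 without replicate 2 or replicate 4. It was 1, Ide, without control female replicate 1 (Mest adjusted p = 0.0849, Fam217a adjusted p = 0.0679) and 0 without control female replicate 2, replicate 3 or replicate 4. Where it was 0, the adjusted p of Mest, Fam217a and Ide lay between 0.0934 and 0.335. With the replicate block in place of batch the count was also 0.

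Lists of immune cell genes were shifted up in Pparg knockout females in camera at its preset correlation, and no shift held with an estimated correlation. The antigen presentation list, which includes the class II genes H2-DMa and H2-Ab1, had a median log2 fold change of 0.76, with all 14 members positive and 7 of 14 higher when adjusted over the list alone (adjusted p = 0.276 with an estimated correlation). Macrophage genes had a median of 0.64 (6 of 16 higher when adjusted over the list alone, adjusted p = 0.546 with an estimated correlation). The same estimated-correlation value of 0.546 was found for pan T cell genes (median 0.68), B cell genes (0.83), type 2 immunity genes (0.55), lipid-associated macrophage genes (0.35), extracellular matrix genes (0.22), endothelial genes (0.38), muscle, pancreas and blood genes (0.35), cell cycle genes (0.53) and immediate early genes (0.23). Type 1 and cytotoxic lymphocyte genes had a median of 0.86 and mature adipocyte genes, led by the leptin gene Lep, a median of 0.17 (adjusted p = 0.652 with an estimated correlation for both). Interferon response genes had a median of 0.38 (adjusted p = 0.548 with an estimated correlation). De novo lipogenesis genes had a median of −0.41, with 18 of 19 members negative and 1 lower when adjusted over the list alone (adjusted p = 0.546 with an estimated correlation). The direction depended on batch: the lipogenesis median was 0.308 in batch 1 alone and −1.142 in batch 2 alone, and that of mature adipocyte genes was 0.955 and −0.233. Over all comparisons, 81 of 103 called lists had a median that moved by more than 1.5 times or turned in 1 batch alone. Single libraries moved several medians. Without control female replicate 1 those of mature adipocyte, endothelial and extracellular matrix genes were −0.16, 0.21 and 0.08, and without replicate 2 mature adipocyte genes had 0.48 and interferon response genes 0.67. Without Pparg knockout female replicate 3 lipogenesis genes had −0.86 and extracellular matrix genes 0.36, and without replicate 4 lipogenesis, interferon response and macrophage genes had −0.19, 0.13 and 0.32.

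In Pparg knockout males no gene was called by edgeR, where 454 genes had an unadjusted p under 0.05. The gene nearest to the threshold was Ide, with a log2 fold change of −0.88 (SE 0.14, adjusted p = 0.0566) and levels of 68 ± 20.6 against 122 ± 8.91 CPM. DESeq2, limma voom with quality weights and limma on the log2 FPKM values each called 1 gene. Leaving out Pparg knockout male replicate 2 gave 1 called gene, and leaving out any other library of the comparison gave 0.

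Lymphocyte and interferon lists were again shifted up in Pparg knockout males at camera's preset correlation. All 20 interferon response genes were positive (median 0.43) and so were all 17 type 1 and cytotoxic lymphocyte genes (median 0.80), each with adjusted p = 0.36 with an estimated correlation. Antigen presentation genes had a median of 0.56 (adjusted p = 0.201 with an estimated correlation), and all 15 immediate early genes were positive with a median of 0.21 (adjusted p = 0.35 with an estimated correlation). Pan T cell genes (median 0.71), regulatory T cell genes (0.40) and the brown-fat-like thermogenic genes (−0.44) each had adjusted p = 0.424 with an estimated correlation. B cell genes had a median of 0.97 and macrophage genes 0.16 (adjusted p = 0.777 and adjusted p = 0.64 with an estimated correlation). No member of these lists was called, over all genes or when adjusted over the list alone. In batch 2 alone B cell genes had a median of 0.19 and camera's direction turned. The macrophage median was 0.02 without control male replicate 4 and 0.41 without control male replicate 1, and the interferon median 0.28 without replicate 2. The thermogenic median was −0.24 without control male replicate 4 and −0.92 without Pparg knockout male replicate 2.

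In Tbet knockout females the genes that build fatty acids fell. They include Acly, which makes cytosolic acetyl-CoA, Acaca and Fasn, which build the chain, and Elovl6 and Scd1, which elongate and desaturate it. Cholesterol synthesis genes such as Sqle and Lss fell with them, 9 of 18. Of 14 antigen presentation genes 6 rose, class II genes among them, and of 20 interferon response genes 4, such as Gbp4, but neither list was called with an estimated correlation. Other rises were Mest, the matrix protease Mmp12 of lipid-associated macrophages, and Sfrp5, a secreted Wnt inhibitor made by adipocytes.

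Of 17824 genes, 104 were higher and 114 lower in Tbet knockout females than in control females, 129 of them by more than 2-fold, 206 of them on autosomes. Of these 218 genes, 37 were in a list and 181 were outside the lists. Of the called genes, 203 passed the mean level and had groups without overlap; over all tested genes 1485 had no overlap, and chance gives 2.86%. In batch 1 alone 619 genes were called, and 119 in batch 2 alone. Without Tbet knockout female replicate 1 the count was 33, and it was 112 without replicate 2, 36 without replicate 3 and 111 without replicate 4. Without control female replicate 1 it was 131, and it was 95 without replicate 2, 113 without replicate 3 and 54 without replicate 4.

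De novo lipogenesis genes had a median log2 fold change of −2.00, with 14 of 19 lower and 17 of 19 when adjusted over the list alone. The list was called at the preset correlation (adjusted p = 4.76e-43), with an estimated correlation (adjusted p = 0.00958) and by fry (adjusted p = 0.000681). Elovl6 (chromosome 3, 129532386 to 129638495) averaged 29.6 ± 5.0 CPM against 647 ± 326 CPM in controls, with a log2 fold change of −4.32 (SE 0.60, adjusted p = 0.0039). Acly (chromosome 11, 100476352 to 100528000) averaged 339 ± 172 against 3221 ± 1341 CPM (−3.28, SE 0.48, adjusted p = 0.0039). Fasn (chromosome 11, 120805958 to 120825166) averaged 1201 ± 899 against 11720 ± 9069 CPM (−3.20, SE 0.59, adjusted p = 0.0146). Acss2, which activates acetate, averaged 75.5 ± 8.15 against 670 ± 155 CPM (−3.15, adjusted p = 0.00547). The pentose phosphate gene Tkt (−2.42), Acaca (−2.65) and the NADPH-producing Me1 (−2.71) fell as well. Scd1 (−2.37) and the citrate carrier Slc25a1 (−2.00) also fell. Srebf1, which encodes the lipogenic regulator SREBP1, had a log2 fold change of −1.02 and was not called (adjusted p = 0.112). Me1, Scd1, Slc25a1 and Srebf1 are named after their values were seen. Acly, Elovl6, Tkt, Acaca and Acss2 kept their calls when any single library was left out. Fasn lost its call without Tbet knockout female replicate 1 (adjusted p = 0.0751) or replicate 3 (adjusted p = 0.068). The list median lay between −2.135 and −1.913 when each library was left out, with 7 to 14 members called, and was −1.894 in batch 1 alone and −2.075 in batch 2 alone. With an estimated correlation the list was called in batch 2 alone (adjusted p = 0.0065) and not in batch 1 alone (adjusted p = 0.161).

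**Figure D1:**
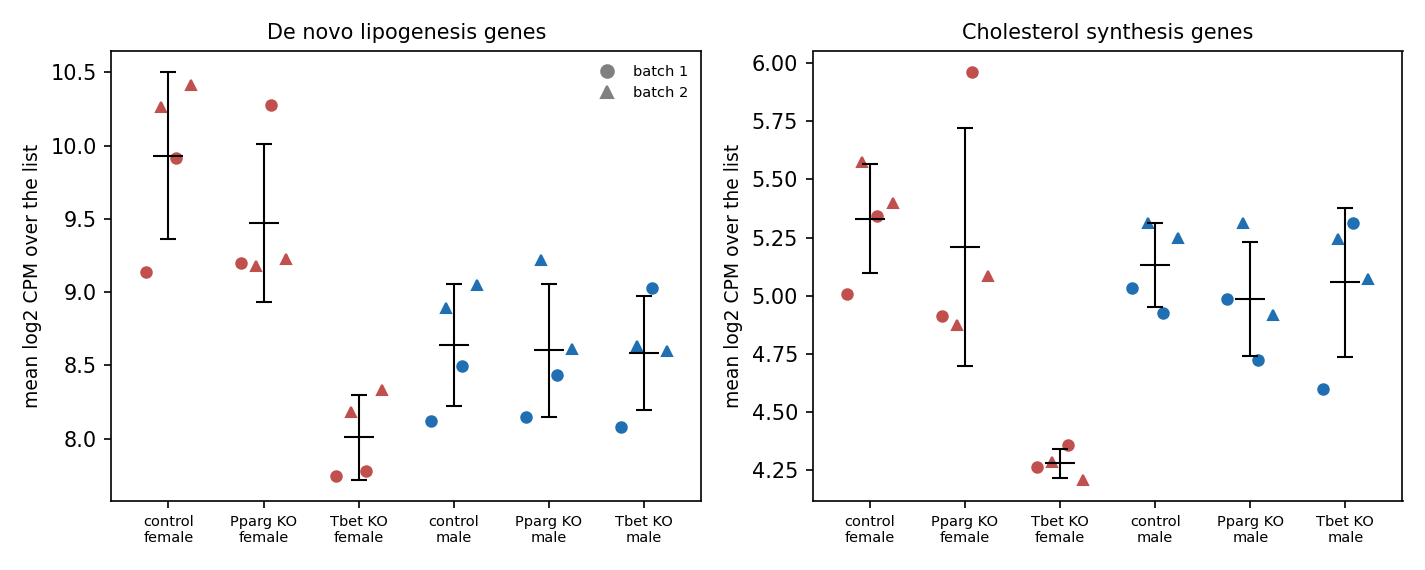
Mean log2 CPM of the de novo lipogenesis and cholesterol synthesis lists in each library by group, with circles for batch 1, triangles for batch 2, red for females, blue for males, and black bars for the mean ± SD of 4 libraries. Lipogenesis in the 4 Tbet knockout female libraries lay between 7.743 and 8.33, below the 9.136 to 10.417 of control females.

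Cholesterol synthesis genes had a median log2 fold change of −1.28, with 9 of 18 lower and 13 of 18 when adjusted over the list alone. The list was called at the preset correlation (adjusted p = 3.6e-20), with an estimated correlation (adjusted p = 0.0429) and by fry (adjusted p = 0.00345). Sqle, which makes squalene epoxide, averaged 12.9 ± 1.57 against 37.1 ± 3.03 CPM (−1.52, adjusted p = 0.00512). Nsdhl (−1.57), Lss (−1.80) and Mvd (−1.48) also fell, while Hmgcs1 (0.07, adjusted p = 0.952), named after its values were seen, was not called. With an estimated correlation the list was called in batch 2 alone (adjusted p = 0.0165), not in batch 1 alone (adjusted p = 0.325), without 8 libraries with epithelial transcripts, of which only control female replicate 1 is in this comparison (0.14), or with a batch term in each sex (0.0681). When each library was left out, 1 to 8 members of the list were called. Nsdhl, Lss and Mvd lost their calls without Tbet knockout female replicate 1 (adjusted p from 0.0651 to 0.0984) or replicate 3 (0.0527 to 0.0972), and Mvd also without Tbet knockout female replicate 4 (0.0528) or control female replicate 3 (0.058).

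Antigen presentation genes had a median log2 fold change of 1.04, with 6 of 14 higher and 8 of 14 when adjusted over the list alone (adjusted p = 0.0707 with an estimated correlation; fry adjusted p = 0.00686). H2-DMa, which loads peptides onto class II molecules, averaged 38.5 ± 15.8 against 16.5 ± 1.98 CPM (1.18, SE 0.21, adjusted p = 0.0115). The class II chains H2-Ab1 (1.11) and H2-Aa (1.11) and the invariant chain Cd74 (1.03) rose too. H2-DMa lost its call without Tbet knockout female replicate 1 (adjusted p = 0.0583) or replicate 3 (adjusted p = 0.0533), and 0 to 7 list members were called when each library was left out. H2-Ab1, H2-Aa and Cd74 lost their calls without the same 2 libraries (adjusted p from 0.0943 to 0.126), control female replicate 3 (0.0509 to 0.0766) or control female replicate 4 (0.0719 to 0.0808). Cd74 also lost its call without control female replicate 1 (0.0606) or replicate 2 (0.0527).

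Interferon response genes had a median of 0.72, with 4 of 20 higher and 11 of 20 when adjusted over the list alone (adjusted p = 0.193 with an estimated correlation). The guanylate-binding protein genes Gbp4 (1.89) and Gbp5 (1.36) and the immunoproteasome genes Psmb9 (1.07) and Psmb8 (1.04) rose, and 0 to 5 members were called when each library was left out. All 4 genes lost their calls without Tbet knockout female replicate 2 (adjusted p from 0.0609 to 0.122), replicate 3 (0.0681 to 0.145), control female replicate 3 (0.053 to 0.109) or replicate 4 (0.0589 to 0.102). Gbp5, Psmb9 and Psmb8 also lost them without Tbet knockout female replicate 1 (0.0651 to 0.118) or control female replicate 1 (0.0549 to 0.11).

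Mageb18, an X-linked gene of the melanoma antigen family, was at least 19.2-fold higher in Tbet knockout females, with 0 counts in control females. Mmp12 averaged 10.6 ± 7.96 CPM against 0.319 ± 0.25 CPM (5.43, SE 1.22, adjusted p = 0.0381), and Sfrp5 117 ± 107 against 5.06 ± 1.64 CPM (4.45, SE 0.81, adjusted p = 0.0137). Mest averaged 196 ± 110 against 23.2 ± 10.1 CPM (3.10, SE 0.52, adjusted p = 0.0064). Other large rises were Ubd, a ubiquitin-like gene induced by inflammatory cytokines (4.30), Crtac1 of cartilage matrix (3.78), the GABA receptor gene Gabrr2 (3.70), the sodium pump gene Atp1a4 (3.40), Ptchd4 (2.81) and Prkag3, a subunit of AMP-activated kinase (1.96). Other large falls were Cyp2f2, a cytochrome P450 gene of airway epithelium (−4.58), Ttc25 of motile cilia (−3.54), the soluble adenylyl cyclase gene Adcy10 (−3.42), H2-Q10 (−2.99) and Ppp1r3b, which targets a phosphatase to glycogen (−2.81). Mageb18, Mest, Sfrp5, Crtac1, Gabrr2, Ptchd4 and Sqle kept their calls when any single library was left out. Ttc25 had 46.5 CPM in control female replicate 1 against 5.79 to 9.18 CPM in the other control females, and without that library its log2 fold change was −2.08 (adjusted p = 0.162); it lost its call without any library but control female replicate 2. Mmp12, Ubd, Atp1a4 and Prkag3 lost their calls without Tbet knockout female replicate 1, replicate 3 or any control female (adjusted p from 0.0504 to 0.157), and Prkag3 also without Tbet knockout female replicate 4 (0.0528). Cyp2f2, Adcy10, H2-Q10 and Ppp1r3b lost theirs without Tbet knockout female replicate 1, replicate 3 or replicate 4 (adjusted p from 0.0528 to 0.134). Control female replicate 2 decided Cyp2f2 (0.0579) and Adcy10 (0.0516), replicate 3 Adcy10 (0.069), and replicate 4 Adcy10 (0.0743) and H2-Q10 (0.0719).

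Other lists were called at camera's preset correlation in Tbet knockout females and not with an estimated correlation. Macrophage genes had a median of 0.75 (7 higher when adjusted over the list alone) and adjusted p = 0.193 with an estimated correlation. Pan T cell genes (0.97), regulatory T cell genes (0.61), cell cycle genes (0.43) and immediate early genes (0.38, with the mRNA-decay factor Zfp36 higher by 0.75) each had adjusted p = 0.401 with an estimated correlation. Type 1 and cytotoxic lymphocyte genes, such as Nkg7, had a median of 1.26 (adjusted p = 0.348 with an estimated correlation). Type 2 immunity genes had a median of 0.55 and endothelial genes 0.49 (adjusted p = 0.324 with an estimated correlation for both). Lipid-associated macrophage genes (0.38) and inflammatory cytokine genes (0.52) both had adjusted p = 0.403 with an estimated correlation. Mature adipocyte genes (0.38) and oxidative phosphorylation genes (−0.24, all 21 negative) both had adjusted p = 0.483 with an estimated correlation. Thermogenic adipocyte genes, with Ucp1 and Cidea, had a median of −1.27 and muscle, pancreas and blood genes 0.54 (adjusted p = 0.246 with an estimated correlation for both). Extracellular matrix genes had a median of 0.33, with Thbs2 higher by 1.56 (adjusted p = 0.336 with an estimated correlation). Zfp36 lost its call without Tbet knockout female replicate 1, replicate 3 or any control female (adjusted p from 0.0534 to 0.121), and Thbs2 without any library but control female replicate 3 (0.0629 to 0.105). Control female replicate 1 moved several medians, and without it they were −0.46 for thermogenic, 0.07 for mature adipocyte, 0.29 for endothelial, 0.22 for extracellular matrix and −0.40 for oxidative phosphorylation genes. Without control female replicate 2 mature adipocyte genes had 0.64 and oxidative phosphorylation genes −0.11. In batch 2 alone the medians of pan T cell (−0.206), inflammatory cytokine (−0.215), immediate early (−0.09) and mature adipocyte genes (−0.157) turned negative, and in batch 1 alone that of oxidative phosphorylation genes was 0.027.

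The lists not called were B cell (median 0.31, adjusted p = 0.374), neutrophil and mast cell (0.33, adjusted p = 0.391), insulin signalling (0.03, adjusted p = 0.712), adipose stromal progenitor (0.25, adjusted p = 0.0643) and mesothelium (0.11, mean −0.47, adjusted p = 0.791). Lymph node stroma (0.26, adjusted p = 0.214), male reproductive tract (2.12, adjusted p = 0.458), female reproductive tract (−0.49, adjusted p = 0.129), mammary and other epithelium (−5.68, adjusted p = 0.318) and circadian clock genes (−0.03, adjusted p = 0.76) were not called either.

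In Tbet knockout males only Ide was called, and it fell. It averaged 66.6 ± 12.7 against 122 ± 8.91 CPM in control males, a log2 fold change of −0.89 (SE 0.14, adjusted p = 0.047). In total 780 genes had an unadjusted p under 0.05, and DESeq2 called 21 genes. It was −1.019 in batch 1 alone, where 6 genes were called, and −0.729 in batch 2 alone, where 0 were. The call was lost, with 0 genes called, without any one of the 8 libraries, namely control male replicates 1, 2, 3 and 4 and Tbet knockout male replicates 1, 2, 3 and 4 (adjusted p from 0.0654 to 0.363).

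**Figure D2:**
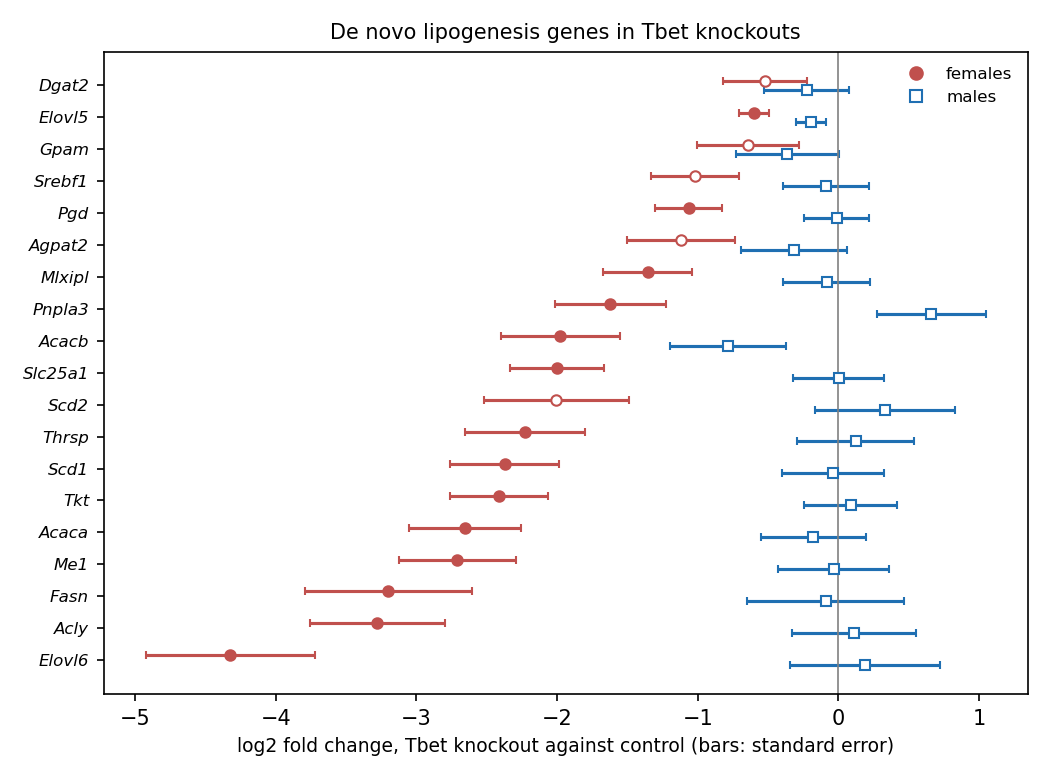
Log2 fold change ± SE of the 19 de novo lipogenesis genes in Tbet knockouts against controls, with red circles for females, blue squares for males, and filled symbols for an adjusted p under 0.05. In females 14 of 19 genes were called lower, and in males none was called.

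B cell genes, with the light chain constant gene Igkc at −3.22, were all negative in Tbet knockout males (17 of 17, median −0.98; adjusted p = 0.538 with an estimated correlation). Antigen presentation genes (median 0.38) and immediate early genes (0.36) were shifted up, with the same adjusted p = 0.538 with an estimated correlation. Macrophage genes had a median of −0.42 (adjusted p = 0.567 with an estimated correlation). Extracellular matrix genes (−0.13) and mesothelium genes (−0.48) both had adjusted p = 0.882 with an estimated correlation. Interferon response genes (0.22) and cell cycle genes (−0.40) both had adjusted p = 0.907 with an estimated correlation. No member was called over all genes, and 1, in the extracellular matrix list, was lower when adjusted over the list alone. The mesothelium median turned to 0.923 in batch 2 alone. The interferon median was 0.05 without control male replicate 2 and 0.41 without replicate 3, and the extracellular matrix median −0.03 without control male replicate 1 and −0.24 without Tbet knockout male replicate 3.

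Ide was lower in all 4 comparisons of a knockout with control, which share their controls within a sex: −0.88 and −0.88 in Pparg knockout females and males, −1.12 and −0.89 in Tbet knockout females and males. It was called in 3 of the 4, with adjusted p = 0.000831 in Tbet knockout females. The average over the 4 comparisons, of 8 control and 16 knockout libraries, was tested after these values were seen. It called 7 genes, 3 higher and 4 lower. Ide had an average log2 fold change of −0.94 (SE 0.08, adjusted p = 4.69e-06), and its controls lay between 105 and 163 CPM while all knockout libraries lay between 48.2 and 91.6 CPM. H2-DMa was higher (0.83, adjusted p = 0.0298) and had no overlap after removing the differences between sexes and batches. Fgfbp3, a growth factor binding protein gene (chromosome 19, 36917550 to 36919599), was lower (−1.02, adjusted p = 0.0298). So was the transcription regulator gene Btaf1 (chromosome 19, 36926079 to 37014057; −0.39, adjusted p = 0.0298). Both lie within 500000 bases of Ide. Cyp2f2 was lower (−2.76, adjusted p = 0.04). Calls of the cholesterol exporter gene Abcg1 (0.58, adjusted p = 0.04) and of Mageb18 (3.25, adjusted p = 0.0453) came from females: in Pparg and Tbet knockout males Abcg1 was at 0.136 and −0.08 and Mageb18 at −0.089 and 0.363.

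**Figure D3:**
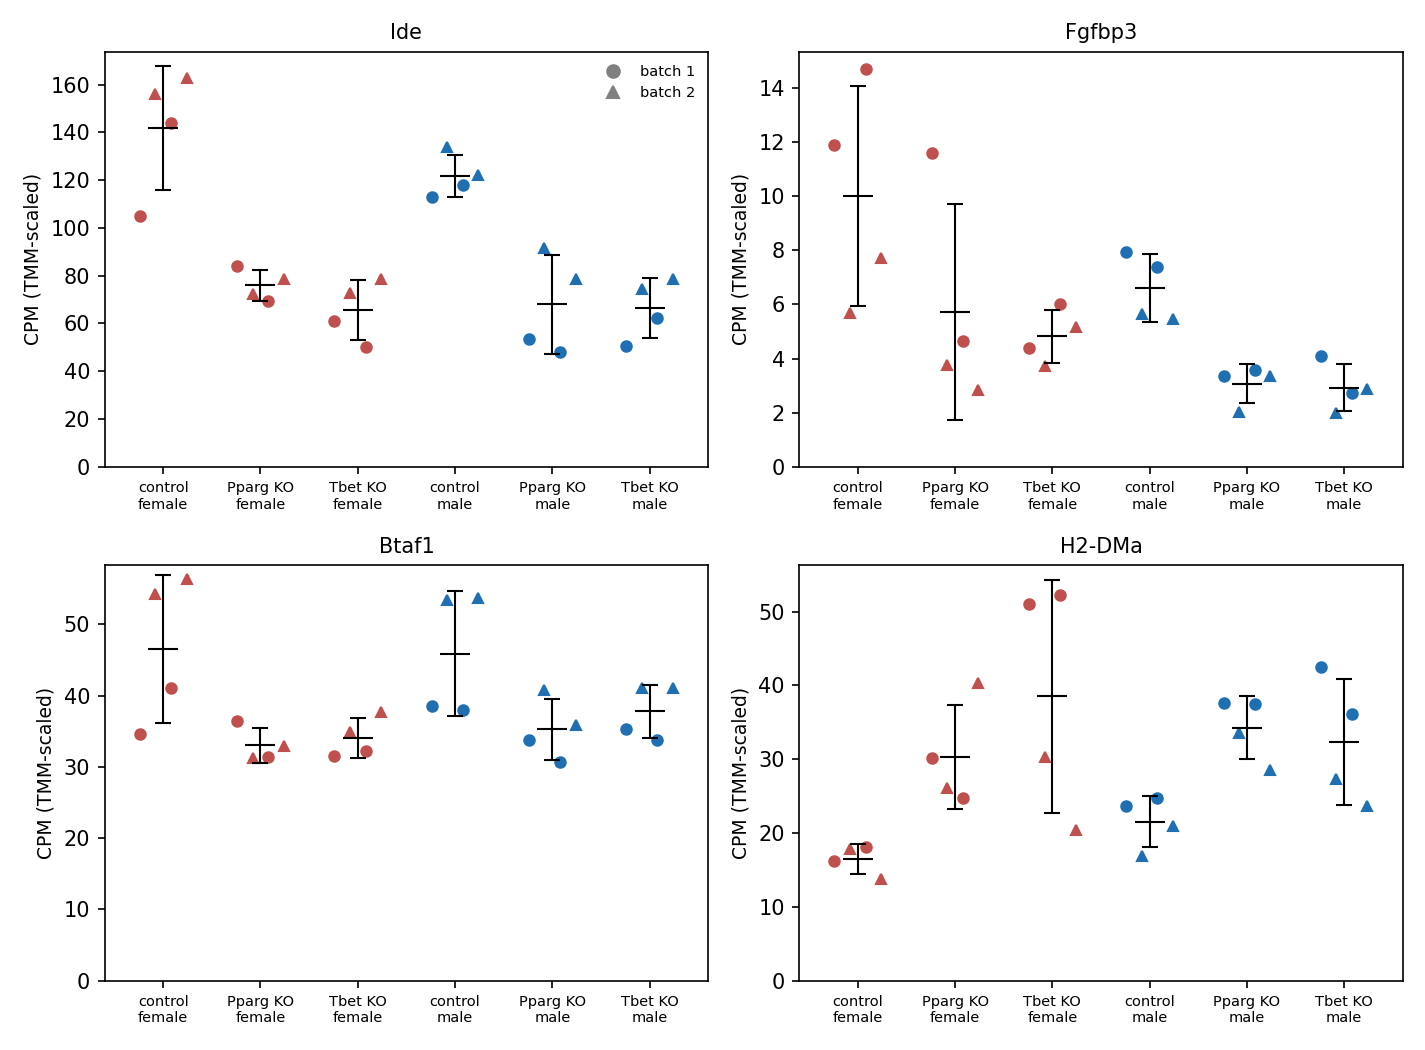
TMM-scaled CPM of Ide, Fgfbp3, Btaf1 and H2-DMa in each library by group, with black bars for the mean ± SD of 4 libraries. Ide lay between 105 and 163 CPM in the 8 control libraries and between 48.2 and 91.6 CPM in the 16 knockout libraries.

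The Tbet knockout effect was called as different between sexes only for Abcg1, a cholesterol exporter gene. In females Abcg1 (chromosome 17, 31057694 to 31117984) averaged 65.6 ± 3.5 CPM in knockouts against 24.9 ± 7.88 CPM in controls, and in males 47.3 ± 6.15 against 50.1 ± 8.59 CPM. The effect in males minus that in females was −1.50 (SE 0.23, adjusted p = 0.0405). It was the only called gene, with 2050 genes at an unadjusted p under 0.05. DESeq2 called 236 genes, limma voom 13 and limma on log2 FPKM 9. Abcg1 was at −1.213 in batch 1 alone and −1.829 in batch 2 alone, where 183 and 2 genes were called. Without control female replicate 1 the count was 8, and without control male replicate 2 it was 1. Without any one of the other 14 libraries compared it was 0, and the adjusted p of Abcg1 lay between 0.0578 and 0.197.

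De novo lipogenesis genes were shifted between the sexes in their Tbet effect, with a median difference of 2.28 and adjusted p = 0.0461 with an estimated correlation (0.0202 in batch 2 alone, but 0.185 in batch 1 alone and 0.0508 with a batch term in each sex). Elovl6 (4.51), Acly (3.39) and Tkt (2.50) had the smallest adjusted p of the list (0.0979 each). No member was called over all genes, and 14 were when adjusted over the list alone. Cholesterol synthesis genes had a median difference of 1.29 (13 called when adjusted over the list alone) and macrophage genes, led by the lysosomal gene Cd68, −1.35 (11 called when adjusted over the list alone). For both, adjusted p = 0.0998 with an estimated correlation and fry gave adjusted p = 0.0469. Other lists were called only at the preset correlation. Interferon response (−0.75), B cell (−1.46), type 2 immunity (−0.43), lipid-associated macrophage (−0.70), antigen presentation (−0.58), thermogenic adipocyte (0.52), female reproductive tract (0.81) and cell cycle genes (−0.82) had adjusted p = 0.369 with an estimated correlation. Type 1 lymphocyte (−1.003), inflammatory cytokine (−0.65) and mammary and other epithelium genes (7.06) had adjusted p = 0.468 with an estimated correlation. The epithelium value turned to −1.425 without 3 libraries (control female replicate 1, control male replicate 1 and Tbet knockout male replicate 4). Mature adipocyte (−0.43) and oxidative phosphorylation genes (0.25) had adjusted p = 0.486 with an estimated correlation. Pan T cell (−0.67), extracellular matrix (−0.49), endothelial (−0.47), and muscle, pancreas and blood genes (−0.76) had, in this order, adjusted p = 0.587, 0.356, 0.37 and 0.153 with an estimated correlation. The mature adipocyte median was −0.19 without control female replicate 1 and −0.71 without replicate 2, and that of oxidative phosphorylation genes 0.39 and 0.11. Without control male replicate 3 the endothelial and interferon medians were −0.27 and −0.47, and without Tbet knockout female replicates 2 and 3 the thermogenic median was 0.31 and 0.87. In batch 2 alone the medians turned positive for pan T cell (0.148), type 1 lymphocyte (0.386), lipid-associated macrophage (0.03) and inflammatory cytokine genes (0.869).

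For Pparg, no gene differed in its knockout effect between sexes in edgeR, limma voom or limma on log2 FPKM, with 1095 genes at an unadjusted p under 0.05 and a smallest adjusted p = 0.435; DESeq2 called 61. Macrophage (−0.45), lipid-associated macrophage (−0.43), mature adipocyte (−0.46), de novo lipogenesis (0.35), extracellular matrix (−0.39), endothelial (−0.46) and cell cycle genes (−0.52) were called at the preset correlation, all with adjusted p = 0.979 with an estimated correlation. The lipogenesis median turned from 1.261 in batch 2 alone to −0.172 in batch 1 alone, and from batch 1 alone to batch 2 alone the mature adipocyte median from −1.251 to 0.185 and the lipid-associated macrophage median from −0.635 to 0.057. Without control female replicate 1 the medians of mature adipocyte, extracellular matrix and endothelial genes were −0.18, −0.23 and −0.27, without control female replicates 2 and 3 those of mature adipocyte and extracellular matrix genes were −0.74 and −0.62. The macrophage median was −0.18 without control male replicate 1, and the lipogenesis median 0.19 without Pparg knockout male replicate 2 and 0.76 without female replicate 3.

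Sex changed far more genes than either knockout. In control males, the estrogen sulfotransferase gene Sult1e1, the leptin gene Lep and 9 of 16 macrophage genes rose against control females. Of 19 de novo lipogenesis genes 10 fell, as did the mesothelial and gonadal regulator Wt1 and the progesterone receptor gene Pgr. Neither list was called with an estimated correlation. Of 17824 genes, 2423 were higher and 2425 lower in control males. The sex genes followed the labels: Xist, which silences the inactive X, averaged 0.437 ± 0.379 CPM in males and 821 ± 257 CPM in females (−11.07). The Y-linked Eif2s3y had a log2 fold change of 10.93, and Ddx3y, Uty and Kdm5d had ratios of 4270 (counting interval 1460 to 20700), 2720 (489 to 108000) and 1140 (315 to 9410).

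Sult1e1 averaged 59.2 ± 15.2 CPM in control males against 0.0193 CPM in control females, a ratio of 2980 (counting interval 826 to 24600). The choline transporter gene Slc5a7 averaged 117 ± 34.6 against 0.119 ± 0.094 CPM (10.01). Large falls were Pcp4, a calmodulin-binding protein gene (−10.99), the relaxin receptor gene Rxfp1 (ratio 980, counting interval 271 to 8100) and Slitrk3 (at least 248-fold lower). The major urinary protein genes Mup14, Mup17 and Mup15 were at least 388-fold, 271-fold and 202-fold lower, and Mup11 and Mup12 had ratios of 820 (280 to 3970) and 964 (173 to 38100). These genes are near-identical paralogs, so reads assigned to one may belong to another. Calb1, a calcium buffer gene, was lower by a ratio of 7250 (1300 to 287000), with 350 CPM in control female replicate 1 and 0.119 to 0.818 CPM in the other control females. The sperm chromatin genes Prm2, Prm1 and Tnp1 were at least 1350-fold, 957-fold and 602-fold higher, with 149, 112 and 70.3 CPM in control male replicate 1. Cuzd1, a gene of secretory epithelium, had a ratio of 1080 (299 to 8930). Without control male replicate 1, Prm2 (log2 fold change 8.746, adjusted p = 0.0837), Prm1 (6.397, adjusted p = 0.0928) and Tnp1 (5.868, adjusted p = 0.144) were not called; with it the values were 12.407, 11.921 and 11.219. Calb1 was at −11.416 and, without control female replicate 1, at −4.561 and not called (adjusted p = 0.0674). Prm2 also lost its call without control female replicate 1 (0.0504) or replicate 3 (0.0646), Tnp1 without any control female (0.0541 to 0.093), Cuzd1 without control female replicate 2 (0.0548) or replicate 4 (0.0597), and Calb1 without control male replicate 1 (0.0561) or replicate 3 (0.0533).

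Among lists in control males, 9 of 16 macrophage genes rose (Cd68 by 2.09; median 0.90) and 8 of 14 lipid-associated macrophage genes (Mmp12 by 7.27, the integrin gene Itgax by 2.96; 9 when adjusted over the list alone). Endothelial genes rose in 10 of 12 (the cadherin gene Cdh5 by 1.53) and cell cycle genes in 8 of 15 (Mki67 by 1.35; 13 when adjusted over the list alone). De novo lipogenesis genes fell in 10 of 19 (Elovl6 by a log2 fold change of −4.00, Acly −3.11, Tkt −2.36) and female reproductive tract genes in 6 of 9 (Pgr −7.80). These 6 lists had adjusted p = 0.599 with an estimated correlation, and fry called all of them. In batch 1 alone the macrophage and endothelial medians were 1.541 and 1.501, in batch 2 alone 0.282 and 0.241, and 5 to 10 endothelial genes were called when each library was left out. Inflammatory cytokine genes rose in 5 of 17 (Ccl2, which recruits monocytes, by 3.23), mature adipocyte genes in 4 of 17, and mesothelium genes fell in 2 of 12 (Wt1 −3.15), with adjusted p = 0.916 with an estimated correlation for these 3. Lep averaged 4495 ± 851 CPM in control males against 472 ± 257 CPM in control females (3.30, SE 0.45, adjusted p = 9.41e-05). The mature adipocyte median of 0.33 was 0.06 without control female replicate 1 and 0.65 without replicate 2, and it turned from 1.755 in batch 1 alone to −0.442 in batch 2 alone. The count of 4848 genes was 5812 in batch 1 alone and 1307 in batch 2 alone. It was 3084 without control male replicate 1, and between 3248 and 5323 without any other library.

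The oviduct glycoprotein gene Ovgp1 was called lower in control males (−8.07), but the value rested on control female replicate 1, with 4630 CPM against at most 4.98 CPM in every other female library; without it the log2 fold change was 0.01. That library also held 376 CPM of the ciliary regulator Foxj1, 236 CPM of the keratin gene Krt8 and 148 CPM of the epithelial gene Epcam, levels read after Ovgp1 was seen. Tbet knockout male replicate 4 held 1140 CPM of Cuzd1 against 0.236 to 54.3 CPM in the other Tbet knockout males. It also held 23.3 CPM of Xist.

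Epithelial transcripts were not confined to single libraries. In 7 of 12 male libraries (control males 2 and 4, Pparg knockout males 1 and 4, Tbet knockout males 1, 2 and 4) Foxj1 lay between 18 and 108 CPM, against at most 0.663 CPM in the other males. In the same 7 libraries Epcam lay between 7.56 and 86.0 CPM against at most 0.899 CPM, Krt8 between 23.2 and 102 CPM against at most 12.1 CPM, and Cuzd1 between 12.5 and 1140 CPM against at most 8.6 CPM. The first principal component of the 24 libraries, with 41% of the variance, lay between 38.19 and 94.32 in these 7 libraries and control female replicate 1, and was at most 22.02 in the others. The male side of every comparison of sexes holds such libraries. Without the 8 libraries with more than 10 CPM of Foxj1, sex changed 4736 genes in controls and 817 in Pparg knockouts, with 2 males left in each; the control males left, replicates 1 and 3, are both of batch 1. In Tbet knockouts only male replicate 3 is left, so the influence of these transcripts on the comparison of sexes stays open there.

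**Figure D4:**
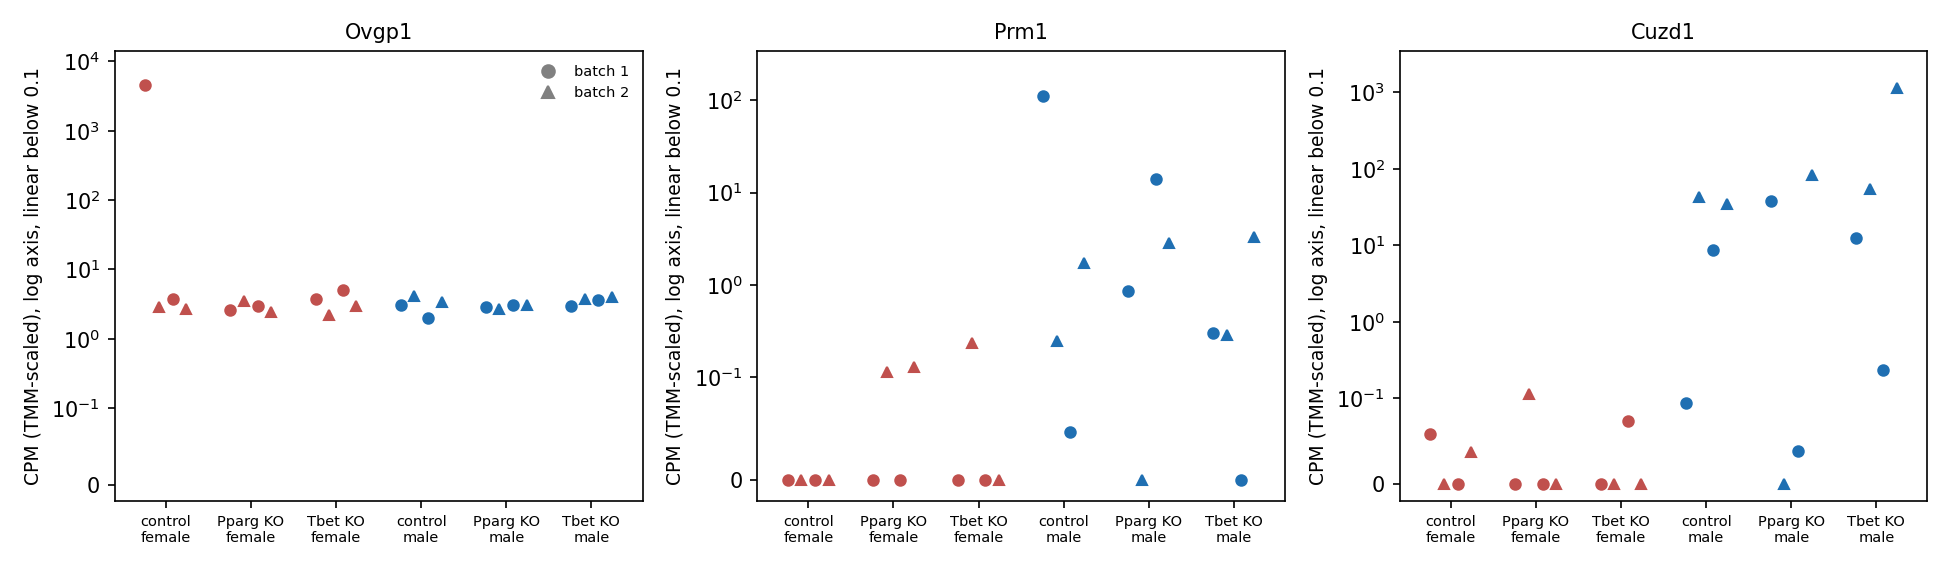
TMM-scaled CPM of Ovgp1, Prm1 and Cuzd1 in each library by group, on a log axis that is linear below 0.1. Ovgp1 reached 4630 CPM in control female replicate 1 and Prm1 112 CPM in control male replicate 1. Cuzd1 reached 1140 CPM in Tbet knockout male replicate 4 and lay between 12.5 and 83.9 CPM in 6 other male libraries.

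In Pparg knockouts, Sult1e1 again rose in males, with 6 of 14 lipid-associated macrophage genes such as Trem2, a lipid receptor gene, and the neutrophil protein gene Lcn2. Wt1, Pgr and 7 of 19 de novo lipogenesis genes fell. Neither list was called with an estimated correlation, and the lipogenesis median was −1.369 in batch 1 alone and −0.142 in batch 2 alone. In total 640 genes were higher and 924 lower. Sult1e1 had a ratio of 6370 (counting interval 1140 to 252000), and other rises were the RNA export gene Nxf3 (7.52), the brush border gene Cdhr2 (5.90), the vesicle secretion gene Cadps (4.91) and Lcn2 (4.81). Sptssb, of sphingolipid synthesis, was at least 721-fold lower, Slitrk3 at least 285-fold and Mup10 at least 140-fold. Pcp4 (−10.16), the homeobox gene Hoxd11 (−8.45), the phosphatase gene Ptpn5 (−8.85), Mup12 (−8.48), Mup17 (−8.39) and Rxfp1 (−8.31) fell too. Lcn2 lost its call without any library but Pparg knockout male replicate 2 (adjusted p from 0.0505 to 0.12), and Sptssb without Pparg knockout female replicate 2 (0.0513), male replicate 1 (0.0623) or male replicate 3 (0.0556). The sex genes followed the labels, with Xist at −10.06, Ddx3y at 9.71, Uty at 8.76, Kdm5d at 9.12 and Eif2s3y at 9.65.

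In the lists of Pparg knockouts, 6 of 14 lipid-associated macrophage genes rose (Mmp12 by 3.54, Trem2 by 1.76; 7 when adjusted over the list alone), 2 of 16 macrophage genes and 2 of 17 inflammatory cytokine genes (3 when adjusted over the list alone). De novo lipogenesis genes fell in 7 of 19 (Tkt −1.85; 8 when adjusted over the list alone), mesothelium genes in 3 of 12 (Wt1 −2.37) and female reproductive tract genes in 3 of 9 (Pgr −6.25; 5 when adjusted over the list alone). All 6 lists had adjusted p = 0.74 with an estimated correlation. Mmp12 lost its call without Pparg knockout female replicates 1, 2 or 3 or male replicates 1 or 2 (adjusted p from 0.0647 to 0.0954), and Trem2 without female replicate 1 (0.0562) or male replicate 1 (0.0617). Cell cycle genes (1 higher, the checkpoint kinase gene Bub1, not called without Pparg knockout female replicates 1, 2 or 3 or male replicate 1, at 0.0538 to 0.0771) had adjusted p = 0.891 with an estimated correlation. Endothelial genes (median 0.43) and oxidative phosphorylation genes (median −0.21) had adjusted p = 0.936 with an estimated correlation, and no member was called. Without Pparg knockout female replicate 3 the lipogenesis median was −0.26 in place of −0.58 and the macrophage median 0.32 in place of 0.50, which was 0.76 without female replicate 4, 0.995 in batch 1 alone and 0.006 in batch 2 alone, with 1 to 6 macrophage genes called when each library was left out. The oxidative phosphorylation median was −0.32 without female replicate 1 and −0.11 without male replicate 4. The count of 1564 genes was 2141 in batch 1 alone and 53 in batch 2 alone. It was 655 without Pparg knockout female replicate 1, 1124 without female replicate 2, 1038 without female replicate 3 and 1774 without female replicate 4. Leaving out males gave 609 without Pparg knockout male replicate 1, 1431 without male replicate 2, 715 without male replicate 3 and 1434 without male replicate 4.

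In Tbet knockouts the fatty acid desaturase gene Scd1 and 5 of 18 cholesterol synthesis genes rose in males. Of 14 stromal progenitor genes 5 fell, among them Lum, a collagen-binding proteoglycan gene, and the growth factor receptor gene Pdgfra. Neither list was called with an estimated correlation. In total 700 genes were higher and 959 lower. Sult1e1 rose by 9.64, and Dao, which oxidises D-amino acids, was at least 566-fold higher. Cuzd1 had a ratio of 10600 (counting interval 2930 to 87300), with 1140 CPM in Tbet knockout male replicate 4 and 0.236 to 54.3 CPM in the other Tbet knockout males. Without that library its log2 fold change was 8.85 in place of 11.65. Cuzd1 lost its call without Tbet knockout female replicate 2 (adjusted p = 0.0513) or replicate 4 (adjusted p = 0.0521), and Dao without any Tbet knockout female or male replicates 1 or 2 (0.0577 to 0.0955). Cadps (7.38) and the zinc transporter gene Slc30a2 (6.59) rose as well. Falls included Pcp4 (−7.73), Rxfp1 (−7.65), Syndig1 (−7.49), Hoxd11 (−6.87), the cell adhesion gene Cntn1 (−6.20) and AW551984 (−6.17). Lrrc4b, Slitrk3 and Ano4 fell by ratios of 307 (counting interval 55 to 12100), 305 (84.5 to 2520) and 160 (44.2 to 1320). Xist was at −7.33, Ddx3y at 9.37 and Eif2s3y at 9.94, and Uty and Kdm5d had ratios of 873 (242 to 7210) and 1710 (308 to 67700).

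Scd1 averaged 20050 ± 3791 CPM in Tbet knockout males against 4148 ± 743 CPM in Tbet knockout females (2.27, SE 0.38, adjusted p = 0.00117). Of 19 de novo lipogenesis genes 2 rose, Scd1 and the triglyceride synthesis gene Dgat2 (3 when adjusted over the list alone). Of 18 cholesterol synthesis genes 5 rose (among them Hsd17b7 by 1.28 and Sqle by 1.14; 12 when adjusted over the list alone). Of 14 stromal progenitor genes 5 fell (Lum −2.42, Pdgfra −1.12), and of 12 mesothelium genes 4 fell (Wt1 −2.90; 6 when adjusted over the list alone). Interferon response genes had a median of −0.65 (Psmb9 fell), endothelial genes 0.35 (the clotting factor gene Vwf rose) and lipid-associated macrophage genes 0.54 (no member called). All 7 lists had adjusted p = 0.8 with an estimated correlation; fry called the cholesterol synthesis and stromal progenitor lists. Dgat2 lost its call without any Tbet knockout female or male replicates 2 or 3 (adjusted p from 0.0584 to 0.165), Psmb9 without any library but female replicate 4 (0.0501 to 0.168), and Vwf without any one of the 8 (0.0513 to 0.166). The lipogenesis median of 0.52 was 0.21 without male replicate 3, and the interferon median was −0.35 without female replicate 2. The count of 1659 genes was 433 in batch 1 alone and 1072 in batch 2 alone. It was 999 without Tbet knockout female replicate 1, 945 without female replicate 2 and 950 without female replicate 4. Without Tbet knockout male replicate 2 it was 1026, without male replicate 3 it was 921, and without any other library it lay between 1267 and 1475.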

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

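These tests were chosen only after the result was seen: the other splits for Pparg knockout females and for the Tbet difference between sexes; all tests on Ide, on both knockouts together and on reproductive tract transcripts; and the tests of lipogenesis genes without control female replicate 1, against mature adipocyte genes and against clock genes.

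Splits of the same libraries into other groups were counted for each comparison. For males against females, 1 of the 35 splits, the real one, called as many genes in each genotype. The real count was 4848 in controls (other splits at most 1364), 1564 in Pparg knockouts (8) and 1659 in Tbet knockouts (33). This argues against chance, within the limits of 35 splits. For Tbet knockout females, 2 of 35 splits called as many genes as the real 218, so chance is not excluded by the count. The other, by batch, called 300 and any further split at most 1. Within the batches 619 and 119 genes were called. Of the 8 splits that part equal replicates of both groups, only the real one called any gene, but 8 are too few to exclude chance. For Pparg knockout females, 7 of 35 splits called as many as the real 3 genes. The batch split called 4155, far more than the real split, which points to a structure of these libraries by batch; the highest of the remaining splits called 879, and 0 and 69 genes were called within the batches. For Pparg knockout males the real count was 0, so all 35 splits are as large by construction and decide nothing. The batch split called 637, again a structure by batch, though in these males batch goes partly with epithelial transcripts. For Tbet knockout males, 3 of 35 splits called as many as the real 1 gene, and the highest of the others was 1. For the difference between sexes, the real count for Pparg was 0, so all 100 drawn splits decide nothing either; they called up to 3714 genes. For Tbet 6 of 100 were as large as the real 1, with up to 2483 genes. Chance is not excluded for the Tbet difference or for Pparg females and Tbet males, and counts that high, from splits that exchange genotypes within each sex, point to a structure of the libraries other than genotype.

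The difference of knockout effects between males and females was called by camera at its preset correlation for 20 lists for Tbet and 7 for Pparg; with an estimated correlation only de novo lipogenesis for Tbet was called. The only gene was Abcg1 (−1.501) for Tbet, called by edgeR. For Tbet, lists whose effect was lower in males than in females were pan T cell (−0.672), type 1 and cytotoxic lymphocyte (−1.003), type 2 immunity (−0.428), B cell (−1.456), macrophage (−1.346), lipid-associated macrophage (−0.698), inflammatory cytokine (−0.65) and interferon response (−0.751). Antigen presentation (−0.58), mature adipocyte (−0.432), extracellular matrix (−0.487), endothelial (−0.469), muscle, pancreas and blood (−0.763) and cell cycle genes (−0.822) had lower effects too. Effects were higher in males for de novo lipogenesis (2.28), cholesterol synthesis (1.291), thermogenic adipocyte (0.521), oxidative phosphorylation (0.254), female reproductive tract (0.807) and mammary and other epithelium genes (7.058). For Pparg the 7 lists were macrophage (−0.448), lipid-associated macrophage (−0.432), mature adipocyte (−0.464), de novo lipogenesis (0.35), extracellular matrix (−0.388), endothelial (−0.463) and cell cycle (−0.517).

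Single libraries lay far from the other 3 of their group in 45 of 369 tests, where chance gives 1 in 20, or 18.4. In 16 of the 45 the other 3 libraries held 0 counts, so that any read flags the library; without tests of that kind 29 of 341 remain, where chance gives 17. Of the 45, 8 were lists, given as mean log2 CPM. Control female replicate 3 was low for inflammatory cytokine genes (0.655, others from 1.475) and thermogenic genes (0.687, others from 2.562). Pparg knockout female replicate 1 was low for mature adipocyte genes (9.432, others from 10.272), replicate 3 high for lipogenesis (10.28, others up to 9.228) and replicate 4 high for lymph node stroma (1.431, others up to 0.875). Epithelial genes were high in control female replicate 1 (5.289, others up to −1.336) and Tbet knockout female replicate 2 (0.64, others up to −1.153), and cell cycle genes were low in control male replicate 3 (1.569, others from 2.062).

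Genes far from their group are given in CPM. In control females these were Ttc25 (46.5), Calb1 (350) and Uty (0.058) in replicate 1, Kdm5d (0.0793) in replicate 2, and Mup14 (26.5) and Pcp4 (411) in replicate 3. In control males they were Prm2 (149), Prm1 (112) and Tnp1 (70.3) in replicate 1, Mup12 (0.0467) in replicate 3 and Calb1 (0.0417) in replicate 4. In Pparg knockout females they were Ptpn5 (70.1) in replicate 1, Sult1e1 (0.0376) in replicate 2 and Ddx3y (0.324) in replicate 4; replicate 3 had Xist at 587 with Mup10 (12.9), Mup12 (14.5) and Mup17 (14). In Pparg knockout males they were Hoxd11 (0.0378) in replicate 1, Mup17 (0.0419) in replicate 2 and Mup12 (0.0379) in replicate 3. In Tbet knockout females they were Ano4 (6.03) in replicate 1, Ppp1r3b (32.4) and Uty (0.233) in replicate 2, and Cuzd1 (0.0732) and Cadps (0.146) in replicate 3. Replicate 4 had Elovl6 (37), Kdm5d (0.101) and Slitrk3 (1.41, others from 9.41). In Tbet knockout males they were Ano4 (0.0711) in replicate 2 and Lrrc4b (0.0473) in replicate 3. Replicate 4 had Xist (23.3), Cuzd1 (1140), Slitrk3 (0.15), Syndig1 (0.601) and Cntn1 (0.376). Values under 0.5 CPM in this paragraph rest on few counts.

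Ide was lower in both knockouts and both sexes. Chance in 8 control libraries is argued against by 100 drawn splits that exchange genotypes within each sex and batch. In 1 of them, the real one, the smallest p of all genes was as small as that of Ide (2.63e-10, against 2.99e-07 at the smallest in other splits). For the count of 7 genes called over both knockouts together, 1 of the 100 splits, the real one, called as many. The highest of the others called 3, which argues against chance. A contiguous copy number change running from Fgfbp3 to Ide is argued against by Cpeb3, which lies between them and averaged −0.043. A copy number change of Ide and Fgfbp3 that leaves out Cpeb3 was not tested and stays open. A candidate explanation is a difference of the chromosome 19 segment between the control line and both knockout lines, since 2 of 10 tested neighbours within 500000 bases were called, against 0.00393 expected. A biological effect of both deletions on Ide stays open, because every control library comes from the control line. A segment on chromosome 19 would not by itself account for H2-DMa on chromosome 17. A difference between the lines elsewhere in the genome was not tested.

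De novo lipogenesis genes were lower in Tbet knockout females. Other-tissue RNA in control female replicate 1 is argued against by the list median without that library, −2.135, and a difference between batches by the smaller of the batch medians, −1.894. Fewer adipocytes in the samples are argued against by the mature adipocyte list, whose median without that library was 0.069. Chance is argued against by 35 splits of the female libraries. Only 1 of them, the real one, had a median as far from 0 (−1.983 against 1.614 in size). No result can be rarer among 35 splits, and they do not adjust for the choice of this list among 29. Another time of day at collection stays open: the clock list gave adjusted p = 0.331 for change in either direction, which does not exclude a shift. A biological effect of losing T-bet in regulatory T cells, or a difference in feeding, was not tested and may account for the fall.

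Reproductive tract transcripts stood out in some libraries of whole tissue, with no sort or gate described. Prm2 also reached 34.3 CPM in Pparg knockout male replicate 3 and 35.9 in Tbet knockout male replicate 4. Foxj1 of ciliated epithelium was over 10 CPM in 7 of 12 male libraries, source not tested. RNA of the testis is a candidate source in control male replicate 1. Of 30 testis genes outside the lists, chosen by tissue, not value, 24 were highest there among 12 males (2.5 expected). RNA of the epididymis is one in Tbet knockout male replicate 4, where 15 of 18 such epididymis genes were highest (1.5 expected). RNA of the oviduct or other epithelium is one in control female replicate 1, where 24 of 24 genes of cilia, chosen after Foxj1 was seen, were highest among the 12 female libraries (2 expected); which ciliated tissue it is stays open. That control female replicates 1 and 4 are libraries of 1 sample, as the source name would have it, is argued against by Ovgp1 at 2.67 CPM in replicate 4; the design gives no biological explanation to test.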

How the results depend on the processing

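The settings with a batch term in each sex, with 1 batch alone, without 3 libraries (control female replicate 1, control male replicate 1 and Tbet knockout male replicate 4) and without the 8 libraries with more than 10 CPM of Foxj1 were chosen only after the result was seen. Unless stated, values are counts of called genes, and the cause was not tested; fewer samples were tested in the batch-alone, summed and leave-one-out settings. Counts not given stayed within 1.5 times the reported count. With DESeq2 the counts were 368 for Pparg females, 1 for Pparg males, 1236 for Tbet females, 21 for Tbet males, 2803 for sex in Pparg knockouts, 2730 for sex in Tbet knockouts, 61 for the Pparg difference between sexes and 236 for the Tbet difference. With limma voom they were 6, 1 and 474 for Pparg females, Pparg males and Tbet females, 2518 and 2856 for sex in Pparg and Tbet knockouts, and 13 for the Tbet difference. With limma on log2 FPKM they were 1 for Pparg males, 340 for Tbet females and 9 for the Tbet difference. Without a batch term they were 0 for Pparg females, 28 for Tbet females, 0 for Tbet males, 2391 for sex in controls, 506 and 522 for sex in Pparg and Tbet knockouts, and 0 for the Tbet difference. With the replicate block in place of batch they were 0 for Pparg females, 128 for Tbet females (125 of them called with batch), 0 for Tbet males and 0 for the Tbet difference. Numbers of Tbet and control females correlated at 0.13 to 0.4 with batch kept and at −0.09 to 0.12 with batch removed, so the numbers pair through batch. Without the low-count filter the counts were 0 for Pparg females, 115 for Tbet females and 0 for Tbet males; with RLE size factors the Tbet difference was 0. With the source name's batch they were 1 for Pparg females and 0 for Tbet males and the Tbet difference. With only the groups compared they were 0, 1, 66 and 0 for Pparg females, Pparg males, Tbet females and Tbet males, 1897 and 533 for sex in controls and Pparg knockouts, and 25 for the Tbet difference. With same-numbered libraries summed they were 85, 1, 1093 and 0 in the 4 knockout comparisons in that order, 3066 for sex in Tbet knockouts and 180 for the Tbet difference.

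With a batch term in each sex the counts were 7 for Pparg females, 1 for Pparg males, 702 for Tbet females, 7282, 4303 and 3787 for sex in controls, Pparg and Tbet knockouts, and 38 for the Tbet difference. Batch changed 7430 genes in females and 9061 in males, and 3374 differently by sex. Without 3 libraries they were 124 for Tbet females, 0 for Tbet males, 2981 for sex in controls and 0 for the Tbet difference. Without 8 libraries, which leaves 1 Tbet knockout male (replicate 3), 2 Pparg knockout males and 2 control males of batch 1, so that values with Tbet males rest on 1 library, they were 0 for Pparg females, 66 for Tbet females, 0 for Tbet males, 817 and 946 for sex in Pparg and Tbet knockouts and 0 for the Tbet difference. In batch 1 alone they were 0 for Pparg females, 619 for Tbet females, 6 for Tbet males, 433 for sex in Tbet knockouts and 183 for the Tbet difference. In batch 2 alone they were 69 for Pparg females, 3 for Pparg males, 119 for Tbet females, 0 for Tbet males, 1307, 53 and 1072 for sex in controls, Pparg and Tbet knockouts, and 2 for the Tbet difference. Leaving out each library gave 0 to 28 for Pparg females, 0 to 1 for Pparg males, 33 to 131 for Tbet females, 0 for Tbet males in every case, 3084 to 5323, 609 to 1774 and 921 to 1475 for sex in controls, Pparg and Tbet knockouts, 0 to 1 for the Pparg difference and 0 to 8 for the Tbet difference.

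Of the 103 gene lists called, 3 were called with an estimated correlation; fry called 18 gene lists, 17 of them among the 103; with an estimated correlation, 1 was called with a batch term in each sex and 3 without 3 libraries, 1 without 8 libraries, 0 in batch 1 alone and 4 in batch 2 alone. Medians turned sign without 3 libraries for mature adipocyte in Pparg females (−0.138), extracellular matrix in Tbet males (0.011) and mammary and other epithelium in the Tbet difference (−1.425). Camera's direction turned, with the median still negative, for macrophage in the Pparg difference (−0.059) and mature adipocyte in the Tbet difference (−0.068) without 3 libraries, and for oxidative phosphorylation in Pparg knockouts by sex (−0.002) with a batch term in each sex. Without 8 libraries directions turned for macrophage in Pparg males (−0.168), interferon response in Tbet males (−0.233) and mammary and other epithelium in the Tbet difference (−4.782), the latter both with 1 Tbet knockout male. Directions of 3 lists turned in batch 1 alone: de novo lipogenesis in Pparg females (0.308) and in the Pparg difference (−0.172), and oxidative phosphorylation in Tbet females (0.027). In batch 2 alone 14 turned. They were mature adipocyte in Pparg females (−0.233), in Tbet females (−0.157), by sex in controls (−0.442) and in the Pparg difference (0.185), B cell in Pparg males (0.19, median still positive) and mesothelium in Tbet males (0.923). In Tbet females they were pan T cell (−0.206), regulatory T cell (0.133, median still positive), inflammatory cytokine (−0.215) and immediate early (−0.09). In the Tbet difference they were pan T cell (0.148), type 1 lymphocyte (0.386), lipid-associated macrophage (0.03) and inflammatory cytokine (0.869). Ovgp1 by sex in controls turned to 0.041 without 3 libraries, 0.435 in batch 2 alone and 0.011 without control female replicate 1 (−8.734 to 0.011 over all libraries left out in turn), the library that holds the transcript. Small changes can be missed: at a simulated log2 change of 0.5, 14.9% of genes were recovered in Tbet females.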

Other observations

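The genes named here were chosen after their values were seen; the test of the sex difference was planned before its result was seen.

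Whether female knockout libraries lie nearer to the male profile than control females do was tested on autosomal genes called by sex in the other knockout, whose libraries that comparison does not share. Of 1458 genes called by sex in Pparg knockouts, 934 (64.1%) moved in Tbet knockout females in the direction of males, 78.2% in batch 1 and 44.1% in batch 2. Of 1545 genes called by sex in Tbet knockouts, 916 (59.3%) moved that way in Pparg knockout females, 60.3% in batch 1 and 55.6% in batch 2. Computed on the female libraries alone, the shares were 62% and 58.9%. Splits of the 8 female libraries as far from an even share numbered 21 of 35 for Tbet and 22 of 35 for Pparg, the real ones included, with up to 80.6% and 78% in other splits, so chance is not excluded and the hypothesis stays open.

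Mest averaged 23.2 CPM in control females, 248 in Pparg knockout females, 196 in Tbet knockout females and 503 in control males. Sfrp5 averaged 5.06, 81.8, 117 and 397 CPM in the same groups, with a log2 fold change of 4.08 in Pparg knockout females that was not called (adjusted p = 0.113). Npr3, a natriuretic peptide clearance receptor gene, averaged 313, 754, 766 and 1600 CPM (1.42, adjusted p = 0.0281 in Tbet knockout females; 1.30, adjusted p = 0.177 in Pparg knockout females).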
